A study of Rattus norvegicus with 6 samples.

How the data were processed

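Total RNA of abdominal aortas with aneurysm from Sprague-Dawley rats was sequenced in 6 libraries, 3 of untreated aneurysms and 3 of aneurysms treated with NP. The labels do not say outright that each library came from a different rat, so p-values measure the spread between these samples.

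The deposited table held 24988 genes, each with a read count and an FPKM value for all 6 libraries. The counts deposited by the authors were whole numbers that had not been normalized. The FPKM values in the same table were computed by the authors and scale counts by gene length and library size. Per the submitters' processing notes, HISAT2 2.0.4 was used, and the series design text names SOAPnuke, a read filter. The tool that counted reads, the genome build, the annotation and the strand setting are not given in the sources used here. In every library fewer genes had a count of 1 than a count of 2, for example 143 and 371 genes in untreated replicate 1, so what 1 count stands for is not settled. Counts and FPKM in the deposited table shared 1 length per gene, within 0.01 on the log2 scale, for 80.6% of the 9168 genes with more than 200 counts in every library. Of the gene names, 2748 were assembled transcripts with MSTRG names, 1874 were clone-based AABR names, and 16795 matched a gene symbol of the GRCr8 RefSeq table. Coordinates were not used because no build is named. A pair of names that a spreadsheet had turned into dates was kept in the tests and left out of the named genes.

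Total counts were 28717872, 27680260 and 30759349 in untreated replicates 1, 2 and 3, and 30939002, 26100468 and 28076224 in treated replicates 1, 2 and 3. Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 16522 genes. Treated libraries were compared with untreated libraries by edgeR 4.0.16's quasi-likelihood test (R 4.3.3) with TMM normalization and group as the only term. Log2 fold changes are treated minus untreated, with standard errors derived from the fold change and its F statistic and with 95% intervals. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. CPM values use TMM-scaled library sizes.

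Before the data were examined, 34 gene lists and a panel of 24 genes often read in aneurysm work were fixed, covering vessel wall cells, matrix, immune and neighbouring cell types, inflammation and metabolism. Of 706 entries in the lists and the panel, 23 were matched to no gene of the table, and 2 were matched through an older symbol. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the 34 lists. Camera asks whether a list's genes rank higher or lower than the other genes. A list score is the mean over its members of log2 CPM after subtraction of each gene's mean over the 6 libraries, and scores were compared by a two-sided exact permutation test, for which 3 libraries against 3 allow no p-value below 0.1.

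The named genes followed a rule fixed at the same time. It takes up to 10 genes per direction past the threshold with a usual symbol, a mean of at least 2 CPM in the higher group, and groups that do not overlap. Open places are filled by the smallest unadjusted p-values in that direction among genes that meet the other conditions. It also takes up to 4 members of each described list with the smallest p-values, and the panel. Genes outside that rule were chosen after their values were seen.

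Counts were simulated for the 16522 kept genes with the means and library sizes of these samples, and 16205 passed the same filter. The gene test was run on these. It recovered 10%, 64%, 86% and 96% of 50 genes each changed 2-fold, 4-fold, 8-fold and 16-fold, with 9 false calls. Noise was drawn independently for each gene, unlike in the real libraries, so these shares may be too high for them. In the real libraries Pck1 was 10.3 times lower in treated aortas and missed the threshold. For the lists, log2 CPM values were simulated with noise independent between genes, and 5 lists were shifted by 1. Camera recovered 5 with the preset correlation and 3 with an estimated correlation. With the preset correlation it made 0 false calls among the 28 lists that shared no gene with the shifted ones. In the real libraries genes within lists were correlated, with an estimate of 0.89 for oxidative phosphorylation genes. The simulation therefore does not show how often camera with its preset correlation calls unshifted lists here.

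The alternatives fixed before the data were examined were DESeq2's median-ratio size factors inside edgeR, no filter on low counts, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom with and without library weights, a minimum log2 fold change of 1, a prior count of 0.5, an estimated correlation, and fry. A fit of limma on log2(FPKM + 1) and a fit with the side of the clock genes as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.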

Results

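The transcriptomes of rat abdominal aortas with aneurysm were compared between 3 untreated libraries and 3 libraries from aneurysms treated with NP, which the series title calls a targeted nanotherapy. The composition of NP and the way the aneurysm was induced are not given in the sources used here. The comparison asks which transcripts differed with treatment. Total counts per library ranged from 26100468 to 30939002, and mitochondrial genes took 8.54% to 13.9% of the counts.

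Among genes with a usual symbol, the 10 of smallest p-value with lower values in NP-treated aortas included Pck1 and Retn of the adipocyte list, and each of the 10 missed the threshold. Over all names the smallest p-value belonged to the clone-based AABR07015881.1, with a log2 fold change of -1.65 (SE 0.22), named after its value was seen. Adrb3, the beta-3 adrenergic receptor of fat cells, averaged 18.2 ± 6.86 CPM in untreated and 2.88 ± 0.986 CPM in treated aortas (mean ± SD, n = 3 each). Its log2 fold change was -2.66 (SE 0.39), and its adjusted p = 0.925 by edgeR missed the threshold. Pck1, which makes phosphoenolpyruvate for glycerol and glucose synthesis, averaged 96.8 ± 39.8 CPM untreated and 9.39 ± 6.77 CPM treated. Acsl1, which activates long-chain fatty acids, averaged 120.4 ± 31.2 CPM untreated and 40.5 ± 11.5 CPM treated. Agt, the precursor of the angiotensins, averaged 43.1 ± 10.1 CPM untreated and 10.5 ± 5.28 CPM treated, a log2 fold change of -2.04 (SE 0.42).

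The other 6 genes at the low end were Retn, Guca2b, Mpo, Arxes2, C6 and Plaat3. Retn, the adipokine resistin, had a log2 fold change of -1.87 (SE 0.40). Mpo, the myeloperoxidase of neutrophil granules, had a log2 fold change of -2.86 (SE 0.64), and Guca2b, the peptide uroguanylin, one of -3.72 (SE 0.88). C6, a component of the terminal complement complex, averaged 63.7 ± 14.0 CPM untreated and 32.3 ± 3.49 CPM treated. Plaat3, an acyltransferase active in fat tissue, averaged 61.5 ± 0.487 CPM untreated and 33.7 ± 4.92 CPM treated, and Arxes2 had a log2 fold change of -1.85 (SE 0.40). Arxes2 is uncertain, since it has a near-identical copy, Arxes1.

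At the high end, Selenow, a small selenoprotein, averaged 30.9 ± 2.81 CPM untreated and 58.2 ± 10.5 CPM treated, a log2 fold change of 0.91 (SE 0.19). Csrp2, a LIM protein of smooth muscle, had a log2 fold change of 0.84 (SE 0.21), and Nexn, the actin-binding nexilin, one of 0.69 (SE 0.21). Pgf, placental growth factor, had a log2 fold change of 0.90 (SE 0.28), and the Wnt receptor Fzd5 one of 1.37 (SE 0.38). The log2 fold changes of Rasl10b, Rassf8, the cation transporter Slc47a1 and Drc3 were 1.49, 0.84, 1.45 and 2.17. Rpl30, at 1.45 (SE 0.42), is uncertain, since ribosomal protein genes share reads with their pseudogenes. In all 20 named genes every treated library lay on 1 side of every untreated library, by the rule that chose them, and each missed the threshold.

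Of 16522 genes, 0 passed an adjusted p of 0.05 by edgeR, and the smallest adjusted p was 0.925. At an unadjusted p under 0.05 there were 319 genes, 97 higher and 222 lower, where chance would give 826. The 3 treated values lay wholly above or below the 3 untreated values in 936 genes (5.67%), against 10% by chance. The biological coefficient of variation was 40.7%. DESeq2 called 29 genes, 28 lower and 1 higher, among them Adrb3, Pck1, Guca2b, Acsl1, Mpo, Agt, Gpd1, Retn, Arxes2 and Plaat3 on the low side and Rasl10b on the high side, and 6 of the 10 splits of the 6 libraries gave at least as many by DESeq2. Limma-voom called 0 genes with library weights and 0 without (489 and 333 at an unadjusted p under 0.05), and limma on log2(FPKM + 1) called 1. That one, AABR07065768.3, named after its value was seen, was at 4.25, 3.92 and 3.21 CPM untreated and 0, 0 and 0.106 CPM treated.

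Of the 34 gene lists, camera with its preset correlation called 12, with 10 lower and 2 higher in treated aortas. With an estimated correlation 0 lists were called, with a smallest adjusted p of 0.361, and fry called 0, with a smallest adjusted p of 0.625. Camera called at least 12 lists in 7 of the 10 splits of the libraries. List scores did not overlap between groups in 5 lists, where chance gives 3.4.

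Adipocyte genes formed the called list with the smallest p-value. Of 20 measured members 18 had a fold below 1, and in 11 every treated library lay below every untreated one. The adipocyte score was 1.48 lower on the log2 scale in treated aortas, from 0.74 ± 0.14 to -0.74 ± 0.88 (exact permutation p = 0.1, the smallest possible). Camera gave an adjusted p of 1.95e-16, and adjusted p = 0.361 with an estimated correlation. Adipoq, the hormone adiponectin, averaged 185 ± 55.8 CPM untreated and 47.1 ± 28.0 CPM treated, and Gpd1, which makes glycerol phosphate for triglycerides, 114 ± 22.4 and 18.2 ± 12.4 CPM. Cfd, the complement protease adipsin, averaged 498 ± 120 CPM untreated and 232 ± 48.6 CPM treated. The lipid droplet genes Plin1 and Cidec had log2 fold changes of -1.98 (SE 0.64) and -1.88 (SE 0.59). Adjusted over the list alone 8 members passed, all lower, namely Adipoq, Cfd, Cidec, Gpd1, Pck1, Plin1, Pnpla2 and Retn. Over all genes tested 0 members passed by edgeR or limma-voom (9 at an unadjusted p under 0.05 by edgeR), and DESeq2 called 3, namely Gpd1, Pck1 and Retn.

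Fabp4 and Cidea, the other 2 adipocyte members, had log2 fold changes of 0.38 (SE 0.48) and 0.37 (SE 0.38). Treated replicate 1 had the lowest adipocyte score, -1.71, against 0.01 and -0.52 in treated replicates 2 and 3. Without it the score difference was -0.9996 and camera's adjusted p was 4.85e-13. After subtraction of each library's list mean, 6 of the 20 members still had groups that did not overlap. Relative to that mean, Cidea, Pparg and Plin4 were higher in treated than in untreated libraries, and Gpd1, Pck1 and Retn were lower.

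**Figure D1:**
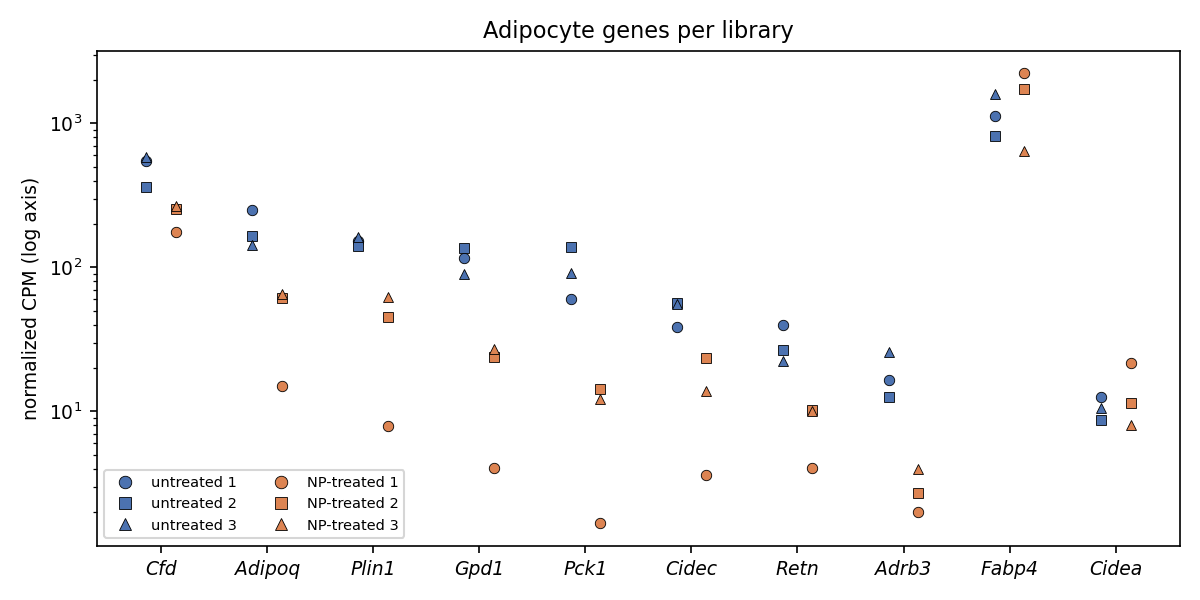
Normalized counts of 9 adipocyte list genes and Adrb3 in each library, in CPM on a log axis, with untreated libraries in blue and NP-treated libraries in orange. Adipoq, Plin1, Gpd1, Pck1, Cidec, Retn, Cfd and Adrb3 separate the groups, while Fabp4 and Cidea overlap.

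Mast cell genes had a fold below 1 in 8 of 9 members, and their score was 1.70 lower (adjusted p = 5.02e-06 by camera, adjusted p = 0.361 with an estimated correlation). The protease genes Cma1, Tpsb2 and Cpa3 had log2 fold changes of -1.68 (SE 0.68), -2.10 (SE 0.96) and -1.84 (SE 0.85), and Fcer1a, a chain of the IgE receptor, one of -2.35 (SE 1.02). Fcer1a was low, at means of 0.916 CPM untreated and 0.176 CPM treated. Without treated replicate 1 the mast cell score was 1.10 lower. Tpsb2 is uncertain, since it can share reads with the tryptase gene Tpsab1. Neutrophil genes had a fold below 1 in 14 of 15 members, with a score 1.11 lower (adjusted p = 8.01e-06 by camera, adjusted p = 0.361 with an estimated correlation). Mpo passed adjusted over the list alone, at 0.0402. Csf3r, the receptor of granulocyte colony-stimulating factor, averaged 22.9 ± 6.93 CPM untreated and 9.74 ± 4.66 CPM treated. Ngp had a log2 fold change of -1.33 (SE 0.81), at low means of 1.22 CPM untreated and 0.486 CPM treated. Its groups overlapped, and untreated replicate 3 held the highest value, 2.58 CPM.

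T and NK cell genes had a fold below 1 in 23 of 24 members (adjusted p = 3.42e-07 by camera, adjusted p = 0.598 with an estimated correlation), with a score difference of -0.73. That difference was -0.28 without untreated replicate 2 and -0.40 without treated replicate 1, and over the fits that each left out 1 library the adjusted p ranged from 3.37e-09 to 0.0200, the highest without untreated replicate 2. Cd8b, of cytotoxic T cells, had a log2 fold change of -0.86 (SE 0.27). Foxp3, of regulatory T cells, had -1.28 (SE 0.52), and Cd6 had -1.79 (SE 0.78). B and plasma cell genes had a fold below 1 in all 15 members (adjusted p = 1.76e-04 by camera, adjusted p = 0.598 with an estimated correlation). Cd79a, Cd79b and Fcrla had log2 fold changes of -2.10, -2.35 and -1.51. Untreated replicate 2 carried much of the lymphocyte signal, with Cd3e at 37.5 CPM, against at most 10.4 CPM elsewhere. Without that library the B and plasma cell list gave an adjusted p of 0.453, and without treated replicate 1 one of 0.176. Over the 6 fits that each left out 1 library it ranged from 2.23e-06 to 0.453.

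Interferon response genes had a fold below 1 in 21 of 24 members, and their score difference was -0.34 (adjusted p = 5.48e-04 by camera, adjusted p = 0.598 with an estimated correlation). The antiviral genes Oas1a, Mx1, Isg15 and Mx2 had log2 fold changes of -0.74, -0.64, -0.50 and -0.80. Without treated replicate 1, whose score of -0.78 was the lowest, the score difference was -0.03 and the adjusted p was 0.369, in a range from 2.68e-06 over the leave-out fits. Without treated replicate 3 the score difference was -0.57. MHC class II genes had a fold below 1 in 9 of 10 members (adjusted p = 0.0349 by camera, adjusted p = 0.598 with an estimated correlation). Cd74, the invariant chain, had a log2 fold change of -0.44 (SE 0.27), and RT1-DOa one of -1.25 (SE 0.50). Ciita and RT1-DMa had -0.33 and -0.26. The MHC class II call ended without untreated replicate 2 (adjusted p = 0.453), treated replicate 2 (0.101) or treated replicate 3 (0.331), in a range from 0.00668.

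Contractile smooth muscle genes had a fold above 1 in 23 of 25 members and a score difference of 0.36 (adjusted p = 1.05e-04 by camera, adjusted p = 0.598 with an estimated correlation). Pln, the calcium pump regulator phospholamban, averaged 20.6 ± 2.87 CPM untreated and 40.1 ± 14.7 CPM treated. Tpm2, a tropomyosin, averaged 327 ± 8.66 CPM untreated and 496 ± 56.1 CPM treated. Lmod1 and Tpm1 had log2 fold changes of 0.83 (SE 0.41) and 0.54 (SE 0.26). Treated replicate 1 had the lowest score of the 6 libraries, -0.48, and without it the score difference was 0.68. Without treated replicate 3 the score difference was 0.13 and the adjusted p was 0.196, in a range from 8.70e-12 over the leave-out fits.

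Glycolysis and hypoxia genes had a fold above 1 in 19 of 21 members, and their score was 0.39 higher (adjusted p = 0.00848 by camera, adjusted p = 0.792 with an estimated correlation). Adm, the vasodilator peptide adrenomedullin, had a log2 fold change of 0.93 (SE 0.41), the glucose transporter Slc2a1 one of 1.88 (SE 0.93), and the lactate exporter Slc16a3 one of 1.73 (SE 0.96). Bnip3, a hypoxia-induced mitophagy gene, had 1.12 (SE 0.68). Treated replicate 1 decided this direction, with a score of 1.32 against at most 0.06 in the other 5 libraries, and without it the list was lower in treated aortas (score difference -0.18, adjusted p = 0.0165). The score difference was 0.70 without treated replicate 2 and 0.64 without treated replicate 3. Without untreated replicate 1 the adjusted p was 0.151, the highest of the leave-out fits, and the lowest was 5.77e-05.

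Fatty acid oxidation genes had a fold below 1 in 13 of 21 members and a score 0.24 lower (adjusted p = 0.0138 by camera, adjusted p = 0.361 with an estimated correlation). Acsl1 passed adjusted over the list alone, at 0.0182. Cpt2, of the carnitine shuttle, had a log2 fold change of -0.51 (SE 0.18), and Cpt1b and Hadh had -0.77 (SE 0.37) and -0.34 (SE 0.16). The adjusted p was 0.159 without untreated replicate 3 and 0.193 without treated replicate 3, in a range from 0.00429.

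Renin-angiotensin genes had a fold below 1 in 7 of 11 members and a score difference of -0.46 (adjusted p = 0.0349 by camera, adjusted p = 0.361 with an estimated correlation). Agt passed adjusted over the list alone, at 0.0188. Enpep, an aminopeptidase that cleaves angiotensin II, averaged 46.3 ± 11.9 CPM untreated and 29.3 ± 4.14 CPM treated. Cma1 is also in the mast cell list. Agtr2, the type 2 angiotensin receptor, had a log2 fold change of 1.63 (SE 0.74) at a mean of 1.11 CPM treated. The call ended without untreated replicate 1 (adjusted p = 0.115), treated replicate 1 (0.129) or treated replicate 3 (0.157), in a range from 0.00266, and without treated replicate 1 the score difference was -0.28.

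Skeletal muscle genes had a fold below 1 in 11 of 16 members (adjusted p = 0.0413 by camera, adjusted p = 0.598 with an estimated correlation). Pygm, the muscle glycogen phosphorylase, averaged 10.4 ± 2.36 CPM untreated and 5.65 ± 1.13 CPM treated. Mylpf, Eno3 and Myh4 had log2 fold changes of -0.98, -0.46 and 1.03. Myh4 was low, at means of 0.351 CPM untreated and 0.723 CPM treated. The call ended without untreated replicate 2 (adjusted p = 0.210), untreated replicate 3 (0.0725), treated replicate 1 (0.354) or treated replicate 3 (0.0554), in a range from 0.0225.

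**Figure D2:**
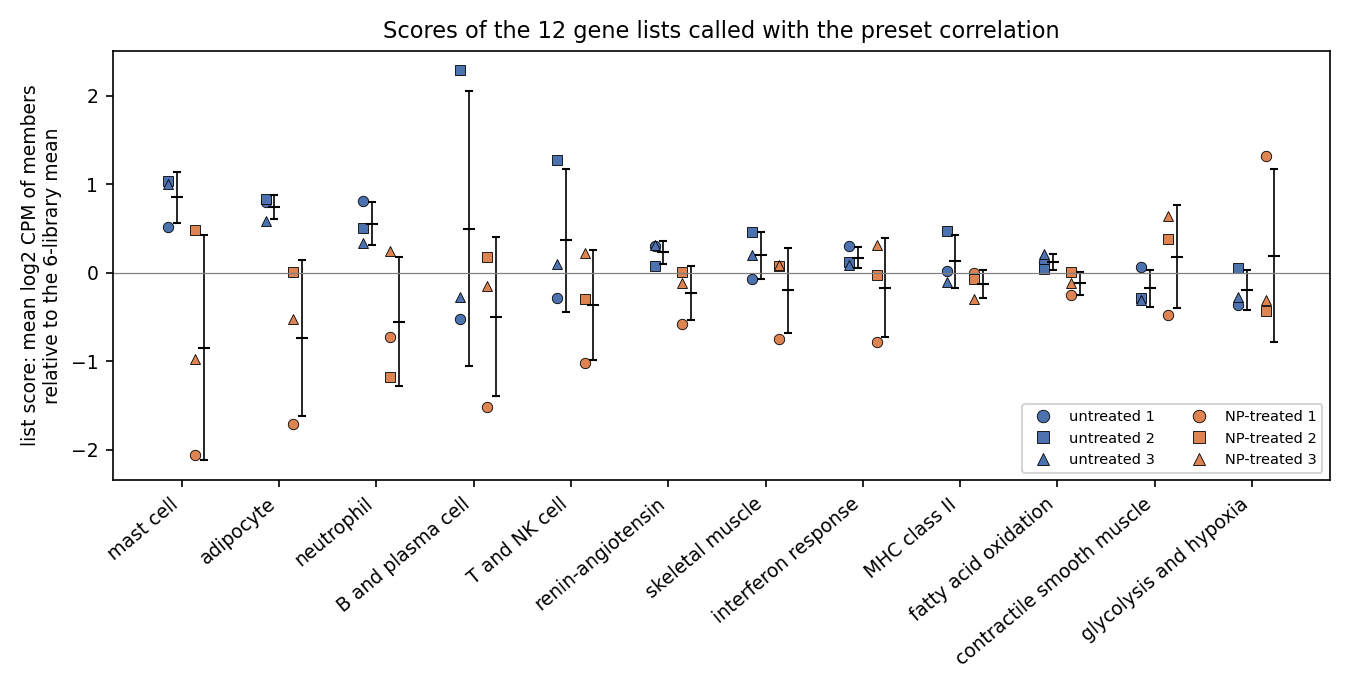
Scores of the 12 called lists, as the mean log2 CPM of members relative to the mean of the 6 libraries, for untreated (blue) and NP-treated (orange) libraries, with bars for group mean ± SD. Adipocyte, mast cell, neutrophil, fatty acid oxidation and renin-angiotensin scores do not overlap between groups, while treated replicate 1 alone lies high for glycolysis and hypoxia.

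The other 22 lists were not called, although 14 of them passed camera in at least 1 fit that left out 1 library. Osteogenic and calcification genes had a fold above 1 in 17 of 21 members, with a camera adjusted p of 0.0509 (0.0295 without untreated replicate 1), and Ibsp, bone sialoprotein, averaged 2.22 ± 2.31 CPM untreated and 14.3 ± 5.71 CPM treated. The member of smallest p-value, Tnfsf11, the osteoclast factor RANKL, lay the other way, at 3.35 ± 1.42 CPM untreated and 1.23 ± 0.35 CPM treated. Protease inhibitors (adjusted p = 0.0634) and TGF-beta signalling (0.0844) had a fold above 1 in 9 of 11 and 16 of 20 members. TGF-beta signalling was higher at 0.00853 without treated replicate 1 and 0.0295 without untreated replicate 1. Cytokines and chemokines gave 0.0844 and a score 0.25 lower, although their mean log2 fold change was 0.00 and their median 0.13. They were lower at 0.0149 without treated replicate 1, and at 0.0426 without treated replicate 3 and without untreated replicate 3. Among them the monocyte-attracting chemokine Ccl7 averaged 31.2 ± 3.51 CPM untreated and 16.4 ± 4.25 CPM treated, and Ccl12 16.6 ± 10.4 and 6.37 ± 2.18 CPM. The adjusted p was 0.0747 for adventitial fibroblast, 0.130 for nerve and ganglion, 0.145 for NF-kB target and adhesion, and 0.147 for erythroid genes. Adventitial fibroblast genes were lower at 4.46e-04 without treated replicate 2 and 0.00246 without untreated replicate 2. Nerve and ganglion genes were higher at 1.35e-04 without untreated replicate 1 and 0.00307 without treated replicate 2. NF-kB target and adhesion genes were lower at 0.0223 without treated replicate 1 and 0.0295 without untreated replicate 1. Erythroid genes were lower at 1.41e-05 without untreated replicate 2 and 0.00511 without treated replicate 3.

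Macrophage genes gave an adjusted p of 0.313, with a fold below 1 in 12 of 23 members, and without treated replicate 1 they were lower, at 1.75e-04. Elastic fibre, collagen and fibrotic matrix, and matrix-degrading protease genes gave 0.925, 0.740 and 0.959, and without treated replicate 3 collagen and fibrotic matrix genes were lower, at 0.00126. Col11a1, a fibrillar collagen, had a log2 fold change of 1.04 (SE 0.39), and Mfap2, of the microfibrils, one of -0.90 (SE 0.39). Antioxidant genes gave 0.284, with extracellular Sod3 at 203 ± 46.3 CPM untreated and 132 ± 16.2 CPM treated, and were lower at 1.75e-04 without treated replicate 1. Endothelial (0.334), NADPH oxidase (0.742), mesothelial (0.816), lysosome (0.925), inflammasome and pyroptosis (0.925), and immediate early and stress genes (0.946) also missed the threshold. Endothelial genes were higher without treated replicate 1 (0.00236) and lower without treated replicate 3 (6.80e-04) or untreated replicate 2 (0.0444). Lysosome genes were lower without treated replicate 1 (0.00505) and higher without treated replicate 3 (0.00126). Proliferation and apoptosis genes both gave 0.226, and proliferation genes were higher without treated replicate 2 (1.19e-05) or untreated replicate 2 (1.41e-05). Oxidative phosphorylation genes gave 0.301, and were lower without treated replicate 1 (3.33e-05) and higher without treated replicate 3 (4.00e-04) or untreated replicate 2 (0.0365).

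For the panel of genes often read in aneurysm, 0 of 22 tested genes passed by edgeR, and 0 passed adjusted over the list alone (smallest 0.546). At an unadjusted p under 0.05 there was 1, and DESeq2 and limma-voom called 0. That gene was Ccl2, a monocyte-attracting chemokine, at 86.9 ± 21.9 CPM untreated and 45.3 ± 24.3 CPM treated, a log2 fold change of -0.94 (95% interval -1.87 to -0.01). Without treated replicate 1 its log2 fold change was -1.47, which passed adjusted over the list alone (0.0394) and missed over all genes (0.974).

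The contractile genes Acta2, Tagln, Myh11 and Cnn1 had log2 fold changes of 0.46 (SE 0.46), 0.39 (SE 0.29), 0.52 (SE 0.43) and 0.08 (SE 0.26). With 1 library left out, Acta2 ranged from -0.28 (without treated replicate 3) to 0.76, Tagln from 0.22 (without treated replicate 2) to 0.60, and Myh11 from 0.05 (without treated replicate 2) to 0.87. Cnn1 ranged from -0.08 (without treated replicate 3) to 0.32, and was -0.03 without treated replicate 2. The upper end of all 4 ranges came without treated replicate 1.

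The matrix genes Eln, Lox, Col1a1 and Col3a1 had 0.65 (SE 0.73), 0.45 (SE 0.66), -0.23 (SE 0.44) and -0.39 (SE 0.31). Without treated replicate 3 these values were -0.32, -0.24, -0.80 and -0.50. Eln reached 1.13 without treated replicate 2 and Lox 0.91 without treated replicate 2 or untreated replicate 1. Lox was 0.21 and Eln 0.40 without untreated replicate 2. Col1a1 was -0.02 without treated replicate 2 and Col3a1 -0.28 without treated replicate 1, where Col1a1 rounded to 0.00.

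Mmp2 and Mmp9, the gelatinases, had -0.59 (SE 0.29) and -0.26 (SE 0.51), and their inhibitor Timp1 had -0.07 (SE 0.44). With 1 library left out, Mmp2 ranged from -0.85 (without treated replicate 2) to -0.44 (without treated replicate 1). Mmp9 ranged from -0.61 (without treated replicate 2) to 0.34 (without untreated replicate 3), and was 0.07 without treated replicate 3. Timp1 ranged from -0.71 (without treated replicate 1) to 0.21 (without untreated replicate 2), and was 0.18 and 0.14 without treated replicates 2 and 3. Mmp12, the macrophage elastase, had 2.43 (95% interval -0.21 to 5.07), but treated replicate 1 held 6349 CPM against a mean of 484 CPM in the other 5 libraries, and without it the value was 0.19. Spp1, osteopontin, likewise had 1.22 (SE 0.64), and 0.12 without treated replicate 1.

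The macrophage marker Cd68 had a log2 fold change of 0.14 (SE 0.38), and the cytokines Il1b and Tnf had -0.54 (SE 0.58) and -0.41 (SE 0.64). With 1 library left out, Cd68 ranged from -0.29 (without treated replicate 1) to 0.39 (without untreated replicate 3), and was -0.03 without untreated replicate 2. Il1b ranged from -1.41 (without treated replicate 3) to -0.17 (without treated replicate 2), and Tnf from -1.24 (without treated replicate 1) to 0.16 (without untreated replicate 2). The oxidase genes Cybb and Nox4 had 0.24 (SE 0.40) and 0.36 (SE 0.44). Cybb ranged from -0.15 (without treated replicate 1) to 0.54 (without treated replicate 3), and Nox4 from 0.00 after rounding (without untreated replicate 2) to 0.88 (without untreated replicate 1).

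Hmox1, Runx2 and Mki67 had 0.17 (SE 0.46), 0.19 (SE 0.20) and 0.06 (SE 0.59). Hmox1 ranged from -0.60 (without treated replicate 1) to 0.47 (without treated replicate 2), and Runx2 from 0.07 (without untreated replicate 1) to 0.31 (without untreated replicate 3). Mki67 ranged from -0.38 (without treated replicate 3) to 0.59 (without untreated replicate 2), and was -0.32 without untreated replicate 3 and -0.01 without treated replicate 1. Il6 was too low to test, with counts of 4, 4 and 4 untreated and 21, 0 and 0 treated. The symbol Pecam1 was matched to no gene of the deposited table, so it could not be tested.

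**Figure D3:**
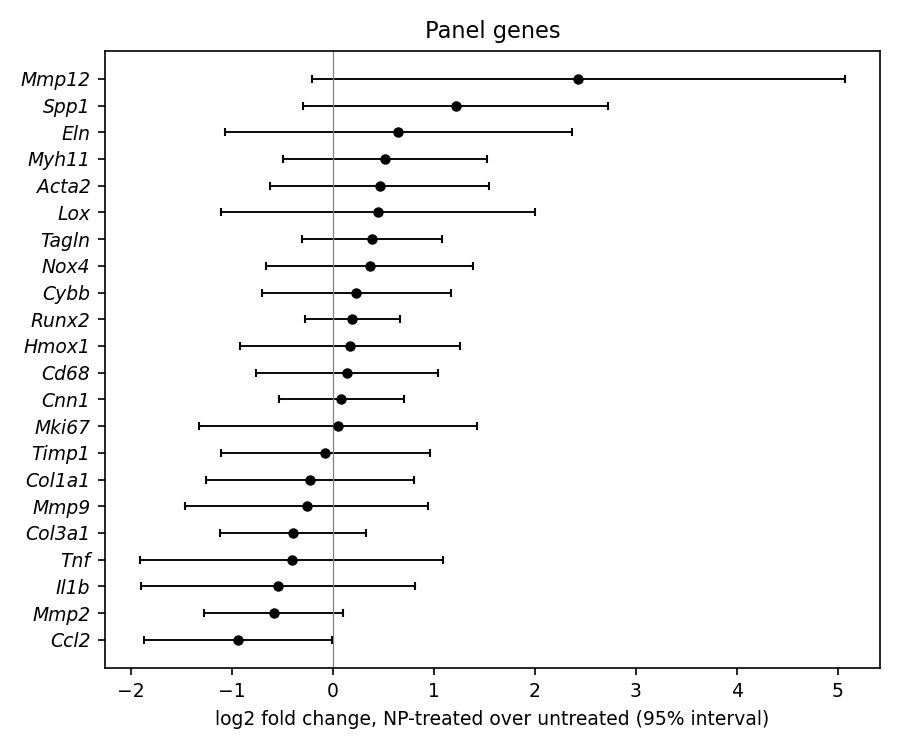
Log2 fold change of each panel gene, NP-treated over untreated, with its 95% interval from edgeR. The Ccl2 interval ends at -0.01, and all other intervals include 0.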

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

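Among the tests of this part, the fit on FPKM and the fit with the clock genes as a covariate were chosen after the data were seen. DESeq2 called 29 genes where edgeR called 0, and leaving out each library moved the DESeq2 count between 17 (without untreated replicate 2) and 111 (without treated replicate 2). Limma on log2(FPKM + 1) called 1 gene, AABR07065768.3, named after its value was seen. The cause of these differences between tools was not tested. The other gene fits gave 0 genes, with 175 to 693 at an unadjusted p under 0.05 over the fits that left out 1 library. The lists called fell from 12 to 0 with an estimated correlation and to 0 with fry, and the other settings gave 11 to 16. The calls of adipocyte, mast cell, neutrophil, and T and NK cell genes held in all 12 alternatives that kept camera with its preset correlation. Glycolysis and hypoxia reversed without treated replicate 1, where camera gave 0.00701 before adjustment, and the fits that left out 1 library ranged from 6.78e-06 to 0.0841. Apart from left-out libraries, MHC class II was lost without the filter (adjusted p = 0.0622), glycolysis and hypoxia, MHC class II and skeletal muscle with the clock covariate (0.0640, 0.0938 and 0.165). Lists gained were protease inhibitors, osteogenic, and cytokine and chemokine genes on FPKM (0.0307, 0.0170 and 0.0170), and collagen, cytokine and chemokine, and erythroid genes with the clock covariate (0.0345, 0.0235 and 2.84e-04). With the replicate block, 0 genes, 13 lists and 0 panel genes were called, and renin-angiotensin was not (adjusted p = 0.0519), while osteogenic (0.0154) and erythroid genes (0.0104) were. Same-numbered libraries deviated with correlations of -0.17, 0.07 and -0.27. These values gave no sign of pairing by number, but so few libraries cannot exclude it, and the labels do not state it. In at least 1 of 14 alternatives, 12 of 22 panel genes and 22 of 135 named list members changed sign. Alternatives planned for normalized values alone were not run, since counts were tested. At this depth and spread, 2-fold changes simulated with noise independent between genes were mostly missed, at 10% recovered.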

Other observations

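Treated replicate 1 differed from the other 5 libraries in genes of several kinds, chosen after their values were seen. The glucose transporter Slc2a1 was 9.90-fold, the lactate exporter Slc16a3 9.18-fold and the lactate dehydrogenase gene Ldha 4.26-fold above the mean of the other 5. Mmp12 was 13.1-fold, the cystatin Cst6 16.8-fold, the oxidized lipoprotein receptor Olr1 7.78-fold and the interleukin 1 antagonist Il1rn 5.66-fold above that mean. The endothelial genes Vwf, Kdr, Nos3 and Ptprb lay below it, with the mean of the other 5 at 7.50, 6.27, 4.78 and 8.53 times the value of treated replicate 1. In treated replicate 1, 67 genes were at least 4-fold above and 234 at least 4-fold below every other library. Its median correlation with the other libraries was 0.919, the lowest of the 6.

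Single libraries also stood out in genes of nerve and B cells, chosen after their values were seen. Dbh, which makes noradrenaline, and the neurofilament gene Nefl were at 29.1 and 26.8 CPM in untreated replicate 1 and at 41.1 and 30.0 CPM in treated replicate 3, against at most 10.9 and 7.51 CPM elsewhere. Untreated replicate 2 held the B cell gene Cr2 at 16.2 CPM, against at most 2.07 CPM in the other 5 libraries.

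In this part, the tests on splits of the libraries (DESeq2's apart), on the single library behind the adipocyte genes, on the largest genes and on macrophages were chosen only after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. All 10 gave at least as many genes by edgeR as the real 0, with 0 the highest of the others, and the same held for the panel (10 splits, real 0, highest other 0). Any split gives at least 0, so the 10 of 10 was fixed in advance for genes and panel and tests nothing. DESeq2 gave at least its 29 genes in 6 of 10 splits, and 708 in the split that sets untreated replicate 1 with treated replicates 2 and 3. That split, singled out because its count was the largest of the 10, gave 2598 genes at an unadjusted p under 0.05 by edgeR against 319 in the real one. What sets its sides apart was not tested. Camera called at least 12 lists in 7 of 10 splits, and the highest other count was 14.

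For the lower adipocyte genes, treated replicate 1 alone is argued against, since without it the list score difference was -0.9996 (untreated SD 0.13). Every treated score lay below every untreated one, but this already held with all 6 libraries and adds no support. Camera with its preset correlation still called the list without treated replicate 1 (with all 6 libraries, adjusted p = 0.361 with an estimated correlation and 0.625 by fry). A smaller share of adipocytes was predicted to leave at most 4 of 20 members with groups that did not overlap relative to the list mean, and 6 were found, against at most 4 in the other splits. That bound was wrong, since members also transcribed in other cells would rise relative to the list mean when the share falls. Of the 6, 3 did so in treated libraries (Cidea, Pparg and Plin4), and only 3 fell relative to it. A smaller share and a change within adipocytes cannot be told apart by this test, because the list mean mixes both kinds of member. A response of adipocytes to NP stays open, and was not tested separately from what was dissected with each aorta.

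For the distance of treated replicate 1, greater depth is argued against, since after thinning to equal totals 282 genes still lay at least 4-fold apart, against 74 in the next library. A few genes taking most counts is argued against, since its 10 largest genes held 15.0% of counts, against up to 17.2% elsewhere. A larger share of macrophages like those of the other libraries would raise no gene more than genes made by macrophages alone. The median excess of glycolysis and hypoxia genes over macrophage list genes was 0.84 on the log2 scale, against -0.34 to 0.22 in the other 5 libraries. Members of the macrophage list moved apart in treated replicate 1. Lgals3 was at 3655 CPM (at most 1882 elsewhere) and Cd163 at 7.73 CPM (at least 17.6 elsewhere). Mmp12, the macrophage elastase, which is outside that list, was 13.1-fold above the mean of the other 5, more than Slc2a1 at 9.90-fold. The list median may therefore not stand for genes made by macrophages alone. The excess does not decide whether a larger share was the source of the glycolysis and hypoxia values. Macrophages in another state, or a state of this aneurysm itself, also stay open, since no test addressed them.

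Clock genes differed between libraries of the same group. Arntl, a core activator of the clock, was at 40.2, 26.1 and 25.95 CPM in untreated replicate 1 and treated replicates 1 and 3, against 9.83, 8.16 and 6.18 CPM in the other 3 libraries. Dbp, which cycles opposite to Arntl, was at 16.9, 21.8 and 33.9 CPM in the former and at 210.2, 228 and 179 CPM in the latter. If the aortas were collected at different times of day, other clock genes should part the libraries alike. Of 5 genes not looked at before, 4 did so in the textbook direction (Npas2, Nr1d2, Tef and Hlf, not Clock), where chance gives 5% for each gene. Clock genes are regulated together, so the 4 are not independent. Collection at different times of day is a candidate explanation, with treated and untreated libraries on both sides, and the labels give no time of collection.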
